A study of Homo sapiens with 12 samples.

How the data were processed

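The libraries came from K562 cells, a human chronic myeloid leukaemia line, that carried a reporter plasmid and a lentiviral library of fusion proteins. Each library member held the doxycycline-dependent DNA-binding protein rTetR and an ordered pair of protein domains, here written as first position + second position. Per the labels, cells of the 2 replicates were infected separately at about 600 cells per member, selected with blasticidin for 7 days and treated with 1000 ng/mL doxycycline from day 8 after infection. Treatment lasted 2 days in the activation screen (reporter line K562 + pDY032) and 5 days in the repression screen (reporter line K562 + pJT039). The third screen, called the unused memory screen in the labels, used K562 + pJT039 with 5 days of doxycycline followed by 5 days without it. Cells were separated into a bound and an unbound fraction, and the domains were amplified from genomic DNA with 33 PCR cycles and sequenced in paired reads of 150 cycles. How the fractions were separated is not given in the sources used here. The submitters' notes speak of ON and OFF cells, and bound was read here as the ON fraction.

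The values used were the deposited raw counts, which per the labels are read pairs summed per library member after the submitters trimmed 30 bases from each end and aligned the reads of each position separately with Bowtie2, whose version is not given in the sources used here. The submitters describe a filter, a floor of 5 reads and a score from total-normalised counts, none of which had been applied in these files, since members with 1 read are listed. No molecular identifiers are stated, so standard errors, intervals and floors cover counting error and the spread between the 2 replicates only, and reads are not independent molecules. The names in the files gave 100 domains and 10000 possible members, of which 9983 had at least 1 read. By name 21 domains were controls (11 tiles of the dystrophin gene DMD and 10 random sequences), 23 were silencer tiles, 51 were short nuclear domains, 3 were KRAB variants and 2 came from NIZP1. The labels state 20 controls with 10 DMD tiles, 30 activators and 50 repressors, and that 6 repressors with design errors were discarded by the submitters. The sources used here do not say which DMD tile is outside that number or which repressors were discarded, so all 100 domains were kept, and all 21 domains named as controls served as controls. Gene names and coordinates (assembly GRCh38) came from a RefSeq table, in which 54 domains matched a gene, 11 of them as DMD tiles. Silencer tiles are written with the Ensembl identifier and tile number of the files, and domains of proteins without a match keep the protein name of the files.

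Members entered a test with at least 5 reads in either fraction and at least 50 reads in both together in each replicate, which is the submitters' filter. Bound and unbound counts were compared with edgeR 4.0.16 under R 4.3.3 (quasi-likelihood fit and test) in a single fit of all 12 libraries, with a block for each screen and replicate and a bound-versus-unbound coefficient for each screen. The fit left 3 residual degrees of freedom. Libraries were scaled by trimmed means (TMM) over pairs of 2 control domains, so every log2 change is relative to control pairs. Adjusted p-values (Benjamini-Hochberg) at or below 0.05 were called. The effect of a single domain was tested in the same way on counts summed over all members that paired it with a control, in both positions, for the 79 domains that are not controls. A score for each replicate, with a floor of 5 reads and centred on the median of the control pairs, gave the mean and SD printed beside an effect (n = 2). Deviation from additivity was the score of a pair minus the median control-partnered scores of both its domains in their positions, tested against 0 with limma 3.58.1. The effect of position was the difference between a domain's control-partnered mean scores in the first and the second position, also tested with limma. Domains were called activating (called and at least 1 in log2 in the activation screen), silencing (called and at most -1 in the repression screen), dual (both) or neither. Mixed pairs were tested with edgeR as the change of a domain's summed effect between control partners and partners of the other class, with dual domains left out. The memory and repression screens were compared as the difference of their coefficients. Medians over control partners required at least 5 partners. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and plots.

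The tests, the classes, the lists of domain families, the rule for named items and most alternatives were chosen before the data were examined. Alternatives added afterwards left DMD tile 31 out of the controls, left out pairs of the same domain, or counted dual domains as activating. Named domains were those called with the same sign in both replicates and both positions, up to 8 with the highest and 8 with the lowest effect per screen. Named members and deviations were the 5 highest and 5 lowest called per screen. For position and for mixed pairs, up to 5 domains changed most each way were named, and for memory the 5 lowest and 5 highest effects among the domains lower in the repression screen. The domain with the largest effect of each list could be named also, and other names are marked where they appear. The lists were KRAB repressors, variant KRAB, HP1 and chromodomain, Polycomb and SAM/MBT, SUMO and E3, homeodomain, corepressor and HDAC, coactivator and Mediator, transcription factor activation domains, WW domain, and other, matched by gene symbol, so that a list can hold any domain of a matched protein. The 23 silencer tiles, which all fall in the list other, were also counted by their name in the files.

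Replicate numbers pair the fractions because, per the labels, each replicate was a separate infection, and each ratio was formed within a replicate. Across members, the deviations of the bound and unbound counts from their group means correlated with r = 0.0718 in the activation screen, 0.204 in the repression screen and -0.0345 in the memory screen. The procedure was tested on simulated data with changes of 1 and 2 in log2. For members it found 7.07% and 53.1% of the changes in the activation screen, 9% and 49.5% in repression, 6% and 58.6% in memory, and 2.02% and 30.4% of the differences between memory and repression. For single domains it found 100% at both sizes in all 4 comparisons, and called 3 of 59 unchanged domains in activation, 2 of 59 in repression, 1 of 59 in memory and 1 of 48 in the difference between memory and repression. For deviations it found 4% and 48.5% in activation and 6.12% and 56.6% in repression. Position changes of 1 were found in 73.5% (activation) and 78.5% (repression) over 10 draws, with 0 to 20 of 20 found in a single draw. Mixed-pair changes of 2 were found for 5 of 5 domains in each screen. The simulated noise was drawn independently for each member, and much of it averages out in sums over partners. A deviation shared by all pairs of a domain in 1 replicate was not simulated. Recovery for single domains and mixed pairs can therefore be lower in the real data. Each screen had 2 replicates per fraction, so p-values rest on the spread between 2 infections. The alternatives were total-count scaling, TMM over all members, DESeq2 1.42.0, other filters and floors (1 and 20 reads, 200 total reads), fits without the block or of a single screen, a limit of 2 SD of the control pairs, other control partners, each position alone, other definitions of the expected score and of the classes, and leaving out each replicate. The result for a further pair of the memory screen is not reported here.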

Results

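Counts of 9983 ordered pairs of protein domains were obtained from 12 libraries, a bound and an unbound fraction in 2 replicates of an activation, a repression and a memory screen. The screens ask how a pair of domains recruited together to a reporter changes its state. Domain names follow the files, as protein and domain family. Total counts ranged from 612999 read pairs (activation, unbound, replicate 2) to 55121999 (activation, bound, replicate 1). The median count per member ranged from 28 in the shallowest library to 1797 in the activation unbound library of replicate 1. Unless another scaling is named, all log2 values below are bound over unbound relative to pairs of 2 control domains. Positive values mean a larger bound share, and each screen had n = 2 replicates. Total counts and TMM over all members move the 0 of a screen, so signs under them are not relative to controls. Under total counts the control domains had a median of -0.91 in activation, 1.85 in repression and 0.45 in memory. Single-domain effects have a standard error (SE) in parentheses where one is given.

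Scores of the pairs spread unequally in the 3 screens. The central 98% of mean scores, between the percentiles 1 and 99, ran from -2.49 to 4.85 in the activation screen, from -5.87 to 1.37 in the repression screen and from -3.29 to 2.16 in the memory screen. Across members, which are not independent replicates, the scores of both replicates correlated with Pearson r = 0.798 and Spearman rho = 0.654 in the activation screen, 0.802 and 0.824 in the repression screen, and 0.318 and 0.351 in the memory screen. Pairs that hold the same domain in both positions were 1.00% of the members and 11.02% of all reads. Their share of the reads ranged from 1.33% (95% Wilson interval 1.32 to 1.33%) in the memory unbound library of replicate 1 to 24.8% (24.7 to 24.8%) in the repression unbound library of replicate 1.

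**Figure D1:**
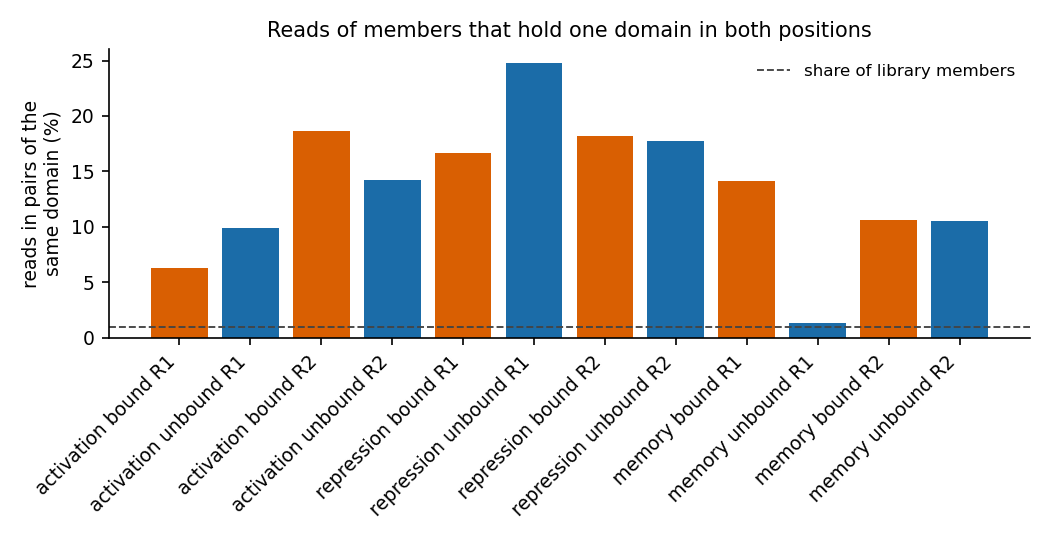
Percent of reads in pairs of the same domain (y axis) in each of the 12 libraries (bars; orange, bound; blue, unbound), with the share of such pairs among the members as a dashed line at 1.00%. All 12 bars lie above the line, from 1.33% to 24.8%.

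Of the single domains next to control partners, 12 rose by at least 1 in the activation screen. The transactivation domain of MYBA, a Myb-family transcription factor, raised the bound share 20.5-fold (log2 4.36, SE 0.16; score 4.17 ± 0.14, SD, n = 2). The domains of NCOA2, a nuclear receptor coactivator (chromosome 8, 70109782 to 70456446), and of FOXO3, a forkhead transcription factor (chromosome 6, 108559825 to 108684774), followed with 15.3-fold (3.93, SE 0.16) and 13.5-fold (3.76, SE 0.17). Tile 22 of ENSG00000179833, named a silencer tile in the files, rose by 3.53 (SE 0.16), and the KRAB domain of ZN473 (gene ZNF473, chromosome 19, 50026005 to 50048776) rose 10.1-fold (3.33, SE 0.16). Smaller increases came from the WW domain of KIBRA, a scaffold of the Hippo pathway (gene WWC1, chromosome 5, 168291645 to 168472303), with 2.10 (SE 0.17; score 1.61 ± 0.42). The KRAB domain of ZN597 (gene ZNF597, chromosome 16, 3432414 to 3443504) rose by 1.79 (SE 0.17) and CRTC2, a coactivator of CREB (chromosome 1, 153947675 to 153958612), by 1.58 (SE 0.14). The lowest effects were those of SUMO3 (-1.28, SE 0.17), a small ubiquitin-like modifier, and of the 3 KRAB variants (-1.27, -1.23 and -1.06). Close to these were ID2 (-1.10, SE 0.17), an inhibitor of basic helix-loop-helix factors, CBX1 (-1.10, SE 0.17), an HP1 protein, MPP8 (-1.03, SE 0.22), a chromodomain protein that binds methylated histone H3, and a silencer tile (-0.92).

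Families were lists of proteins, so a list can hold other domains of them. Of 11 domains in the coactivator and Mediator list, 8 rose in the activation screen and 1 fell, against 3 higher and 7 lower under total-count scaling. Of 5 domains in the transcription factor list, which holds a DNA-binding domain of CREM and the Notch domain of NOTC2, 4 rose and 1 fell (CREM, -0.86, SE 0.24), against 2 and 2 under total counts. Of 5 domains in the variant KRAB list, which holds the C2HR domain of NIZP1, 4 rose and 0 fell (2 and 3 under total counts), and of 5 WW domains 3 rose and 0 fell (1 and 3 under total counts). Silencing families fell and stayed below 0 under each scaling tried: 3 of 4 in the KRAB repressor list (the KRAB variants, but not the DUF3669 domain of ZN777), 3 of 4 HP1 and chromodomain proteins, 2 of 3 Polycomb and SAM/MBT domains and 2 of 2 SUMO and E3 domains, the last including HERC2 (-0.75), a ubiquitin ligase. Of the 2 homeodomains edgeR called 0 (0 at an unadjusted p of 0.05, 1 by limma and 0 by DESeq2), and in the corepressor and HDAC list 1 of 2 fell (TOX, an HMG-box protein). That call was lost with DMD partners, in each position alone and without either replicate. Of the 36 other domains 6 rose and 15 fell, and of the 23 silencer tiles 3 rose and 12 fell, where total counts left 1 of the 36 higher and 32 lower. The counts adjusted over the list alone were the same except for 4 WW domains higher in place of 3 and 3 Polycomb and SAM/MBT domains lower in place of 2. In all, edgeR called 25 of 79 domains higher and 28 lower at an adjusted p of 0.05, and 12 were at or above 1. Total-count scaling moved the median of all members by -1.09, and TMM over all members moved it by 0.07. The effects of the control domains had an SD of 0.19 without DMD tile 31, which itself stood at 2.09, and position 2 alone gave 34 called domains in place of 53.

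Among pairs in the activation screen, the highest held at least 1 domain of the activating or dual class. FOXO3 + ZN597 reached 7.03 (SE 1.83), although its scores were 6.94 and 1.43 in the replicates and the unbound library of replicate 2 had 0 reads of it. Tile 13 of ENSG00000205571 + MYBA reached 6.68 (SE 0.57) and the same tile + FOXO3 6.06 (SE 0.81). Pairs with the SH3 domain of ANM2, a protein arginine methyltransferase, were NOTC2 + ANM2 at 6.18 (SE 0.78) and FOXO3 + ANM2 at 6.06 (SE 0.81). In the unbound library of replicate 2 the pairs with tile 13 had 1 and 4 reads and those with ANM2 1 each, below the floor of 5. Their scores in replicate 1 were 6.62 and 5.95 with tile 13, and 5.55 and 5.57 with ANM2. The lowest were random control 297 + HXA13 (-4.71, SE 1.31), ID2 + YAF2 (-3.86, SE 1.15), DPF1 + GSX1 (-3.66, SE 1.22), a pair of silencer tiles (-3.38, SE 1.01) and random control 124 + CREM (-3.32, SE 0.88). Of 9063 members tested 1344 were higher and 860 lower (1020 and 4572 under total counts), and of 5598 pairs without a control 915 were higher and 625 lower. Of 417 control pairs 26 were called, and of the 376 without DMD tile 31 this was 3 (0.798%). The 2204 calls became 936 without replicate 1 and 1081 without replicate 2. FOXO3 + ZN597 and the lowest pairs lost their calls without either replicate, except DPF1 + GSX1 without replicate 2. This pair was -1.69 without replicate 1 and -1.97 without the block, and lost its call in both cases and without DMD tile 31 among the controls.

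In the repression screen, the KRAB variants had the lowest bound shares of the single domains. KRAB domains recruit the corepressor TRIM28 as a class, and the variant P21506 lowered the bound share 26.2-fold (log2 -4.71, SE 0.21; score -4.94 ± 0.98, SD, n = 2), with -4.70 (SE 0.18) and -4.41 (SE 0.19) for the other KRAB variants. Tile 18 of ENSG00000100307 followed (-3.79, SE 0.16), then SUMO3 (chromosome 21, 44805617 to 44818062; -3.78, SE 0.19), another silencer tile (-3.75, SE 0.18), CBX1 (chromosome 17, 48070059 to 48101478; -3.70, SE 0.18) and YAF2, a subunit of Polycomb repressive complexes (chromosome 12, 42157104 to 42238248; -3.63, SE 0.21). Higher bound shares were called for DPF1 (0.67, SE 0.17) and SMRC2 (0.39, SE 0.13), both subunits of SWI/SNF remodelling complexes, and for DPY30 (0.49, SE 0.18), a subunit of histone H3 methyltransferase complexes. The other was ZN597 (0.55, SE 0.17), whose score was below 0 in the second position in replicate 2. The calls of DPF1, DPY30 and SMRC2 were lost with limma on mean scores, those of SMRC2 and DPY30 also with DMD partners (0.05 and 0.28). SMRC2 lost its call without either replicate and in the second position alone, and DPY30 without replicate 1.

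Several activating domains, including the 5 with the highest activation effects, also had lower bound shares in the repression screen. FOXO3 fell by 1.91 (score -1.79 ± 0.60), MYBA by 1.32 and NCOA2 by 1.27, tile 22 of ENSG00000179833 by 1.36, ZN473 by 1.14, and SMCA2, an ATPase of the SWI/SNF complexes, by 1.30, and these 6 domains formed the dual class. Under total-count scaling FOXO3 stood at -0.08 and ZN473 at 0.69, and under TMM over all members at 0.05 and 0.82. The control domains had medians of 1.85 and 1.98 under these scalings, so both domains stayed below the controls. All 5 domains in the transcription factor list fell, against 3 higher and 0 lower under total counts. Of 11 coactivator and Mediator domains 3 rose and 5 fell, and of 5 domains in the variant KRAB list 1 rose and 4 fell, NIZP1 C2HR among them, against 10 and 0, and 5 and 0, under total counts. Of 5 WW domains 3 fell and of 2 homeodomains 2 fell, against 5 and 1 higher and 0 lower under total counts. Of the silencing families, 4 of 4 domains in the KRAB repressor list fell (3 under total counts, with ZN777 DUF3669 above 0), and 3 of 4 HP1 and chromodomain proteins fell (CHD3 was higher under total counts). Both SUMO and E3 domains fell under each scaling, and 3 of 3 Polycomb and SAM/MBT domains fell (1 under TMM over all members). TOX fell by 2.52 as 1 of 2 in the corepressor and HDAC list, 25 of 36 other domains fell, and 16 of 23 silencer tiles fell with 0 higher, where total counts left 17 of the 36 higher and 15 lower. All counts adjusted over the list alone were the same. With limma on mean scores, 3 of 11 coactivator and Mediator, 1 of 5 variant KRAB list and 0 of 5 WW domains were called, in place of 8, 5 and 3. DESeq2 called 8, 4 and 2 of them. Over all domains edgeR called 57 of 79 lower and 4 higher, and 41 were at or below -1. Relative to control pairs the median of all members was -1.96, a shift of 1.83 under total counts and of 1.97 under TMM over all members.

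**Figure D2:**
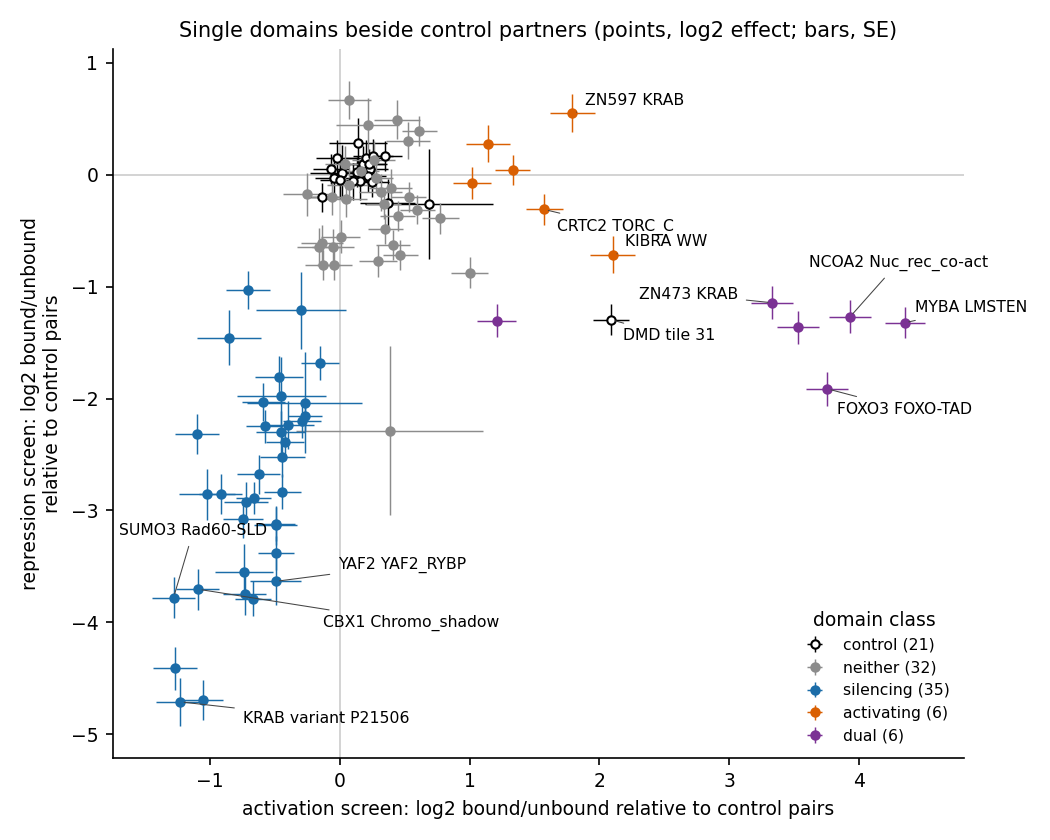
Log2 bound over unbound relative to control pairs of the 100 domains next to control partners in the activation screen (x axis) and the repression screen (y axis), with SE as bars and colours by class. The 6 dual domains lie at 1.21 to 4.36 in the activation screen and below -1 in the repression screen. Under total-count scaling FOXO3 stands at -0.08 and ZN473 at 0.69 in the repression screen, where the control domains have a median of 1.85.

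Pairs with the lowest bound share in the repression screen combined a silencing domain with a partner of varied class. They were KRAB variant P21506 + ANM2 (-7.09, SE 0.89), a silencer tile + ID2 (-7.08, SE 1.47) and ATF1, a CREB-family factor, + a silencer tile (-6.94, SE 1.03). The others were SUMO3 + SSX2 (-6.88, SE 1.17) and tile 13 of ENSG00000205571 + CBX1 (-6.84, SE 1.29). In this order they had 3, 0, 6, 4 and 1 reads in the bound library of replicate 2. All but the ATF1 pair were thus below the floor of 5 there. Their scores in replicate 1 were -5.94, -5.46, -5.81, -5.28 and -5.96. The highest were DMD tile 255 + random control 372 (2.76, SE 1.05), CXXC1 + random control 385 (2.23, SE 0.67), PCGF2 + CXXC1 (1.91, SE 0.68), DMD tile 251 + DMD tile 259 (1.87, SE 0.74) and BTK + TERF1 (1.86, SE 0.64). Of 9062 members tested edgeR called 5124 lower and 47 higher (2811 and 2593 under total counts, 2688 and 2846 under TMM over all members), and of 5593 pairs without a control 3721 lower and 19 higher. Of 416 control pairs 27 were called, and 3 of the 376 without DMD tile 31. The highest pairs lost their calls without replicate 1, except CXXC1 + random control 385, and without replicate 2, except BTK + TERF1.

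Pairs of activating domains exceeded the sum of their median control-partnered scores in the activation screen, and pairs of a dual with a silencing domain fell short of it. These medians can lie below the effects on summed counts given above. BTK had 0.63 in the first and 0.20 in the second position, against an effect of 1.14 on summed counts. An excess over the sum is therefore not an excess over the summed-count effects. The median deviation of 28 pairs of activating domains was 2.15 ± 0.02 (SD, n = 2; median score 3.61 against an expected 1.81), with 19 above and 0 below the sum. Pairs of an activating domain with one of neither class deviated by 0.97 ± 0.14 (162 of 366 above, 14 below), and pairs of neither class by 0.28 ± 0.04 (200 of 975 above, 14 below). The SH3 domain of BTK, a tyrosine kinase (chromosome X, 101349450 to 101390796), was in 4 of the 5 pairs farthest above: U2AF4 + BTK (5.16, SE 0.36), BTK + ABL1 (5.11, SE 0.32), WWP2 + BTK (5.11, SE 0.46) and BTK + WWP2 (4.53, SE 0.36). The other pair was ABL1 + a silencer tile (4.52, SE 0.25). Pairs of dual domains scored 3.78 against an expected 7.54 (deviation -3.71 ± 0.03, 23 of 30 below; -0.21 against the stronger effect), as in MYBA + FOXO3 with 2.02 against 8.42 (deviation -6.40, SE 0.33) and MYBA + tile 22 of ENSG00000179833 (-5.64, SE 0.27). The highest mean score of any pair in this screen was 6.32, so the expected 7.54 and 8.42 lay above every mean score seen. Whether the screen has an upper limit was not tested, so this shortfall cannot be told apart from such a limit. Other pairs far below the sum were MYBA + a silencer tile (-5.83), another silencer tile + MYBA (-5.72) and MPP8 + FOXO3 (-5.77, SE 0.87). In this order, their poorer replicates had 83, 214 and 65 reads. With a silencing partner, dual domains scored -0.80 against 2.97 (deviation -3.51, 305 of 385 below) and activating domains -0.76 against 0.00 (-0.88, 84 of 349 below). Dual domains with activating ones deviated by -0.25 (14 above and 16 below of 71), which became 0.77 when the stronger effect was the expectation, and with neither class by -0.28 (64 above and 120 below of 383). Pairs of silencing domains scored -0.84 against -1.69 (deviation 0.85, 206 of 928 above), and silencing domains with neither class deviated by -0.06 (61 above and 40 below of 2005). limma called 740 of 5598 pairs above and 627 below the sum.

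In the repression screen, pairs of silencing domains did not reach the sum of their median control-partnered scores. Their median score was -4.00 against an expected -6.62 (deviation 2.74 ± 0.01, SD, n = 2), with 699 of 927 above the sum and 0 below, and against the stronger of both effects the median deviation was -0.02. The lowest mean score of any pair in this screen was -7.11, and a score of -8.87 occurred in 1 replicate. Sums below -7.11 lay outside the mean scores seen. The median sum of -6.62 lay within them, but below their percentile 1 of -5.87. Whether the screen has a lower limit was not tested, so this shortfall cannot be told apart from such a limit. Dual with silencing domains scored -3.49 against -4.85 (1.30 ± 0.26, 201 of 383 above), and -0.04 against the stronger effect. Pairs of dual domains deviated by 0.79 (12 of 30 above), and by -0.26 against the stronger effect. Activating with silencing domains deviated by 0.66 (102 of 353 above) and neither with silencing domains by 0.33 (450 of 2020 above). Below the sum lay pairs of neither class (-0.37, 264 of 972 below), activating with neither class (-0.34, 60 of 359 below), dual with neither class (-0.30, 79 of 377 below) and pairs of activating domains (-0.49, 5 of 25 below). Activating with dual domains deviated by -0.06, with 3 above and 3 below of 68. The largest deviations above the sum were MPP8 + SSX2 (8.78, SE 1.34), YAF2 + a silencer tile (7.33, SE 1.07) and SSX2 + YAF2 (6.84, SE 1.39). Next were a silencer tile + SSX2 (6.69, SE 0.35) and SSX2 + a KRAB variant (6.55, SE 1.11). The poorer replicates of these pairs had 78, 98, 69, 1243 and 107 reads, in this order. The sums for MPP8 + SSX2 (-7.70), YAF2 + a silencer tile (-8.26) and a silencer tile + SSX2 (-7.14) lay below -7.11. Any mean score seen would have exceeded these sums. SSX2 is a cancer-testis protein whose own effect of -2.29 (SE 0.76) was not called (adjusted p = 0.072). Farthest below were KMT2B + CHD3 (-3.58, SE 1.27), DPF1 + CXXC1 (-3.28, SE 1.05), CACO1 + KS6B2 (-3.15, SE 0.23), a silencer tile + NIZP1 KRAB (-2.99, SE 1.11) and NOTC2 + KIBRA (-2.99, SE 0.59). In this order, their poorer replicates had 55, 109, 8034, 148 and 598 reads. Against the stronger effect KMT2B + CHD3, DPF1 + CXXC1 and the pair with NIZP1 KRAB lost their calls. KMT2B + CHD3 also lost it at a floor of 1 read, and the NIZP1 KRAB pair at a floor of 20 reads and with the mean over partners. limma called 1552 of 5593 pairs above and 537 below the sum, and 478 above and 543 below the stronger effect.

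**Figure D3:**
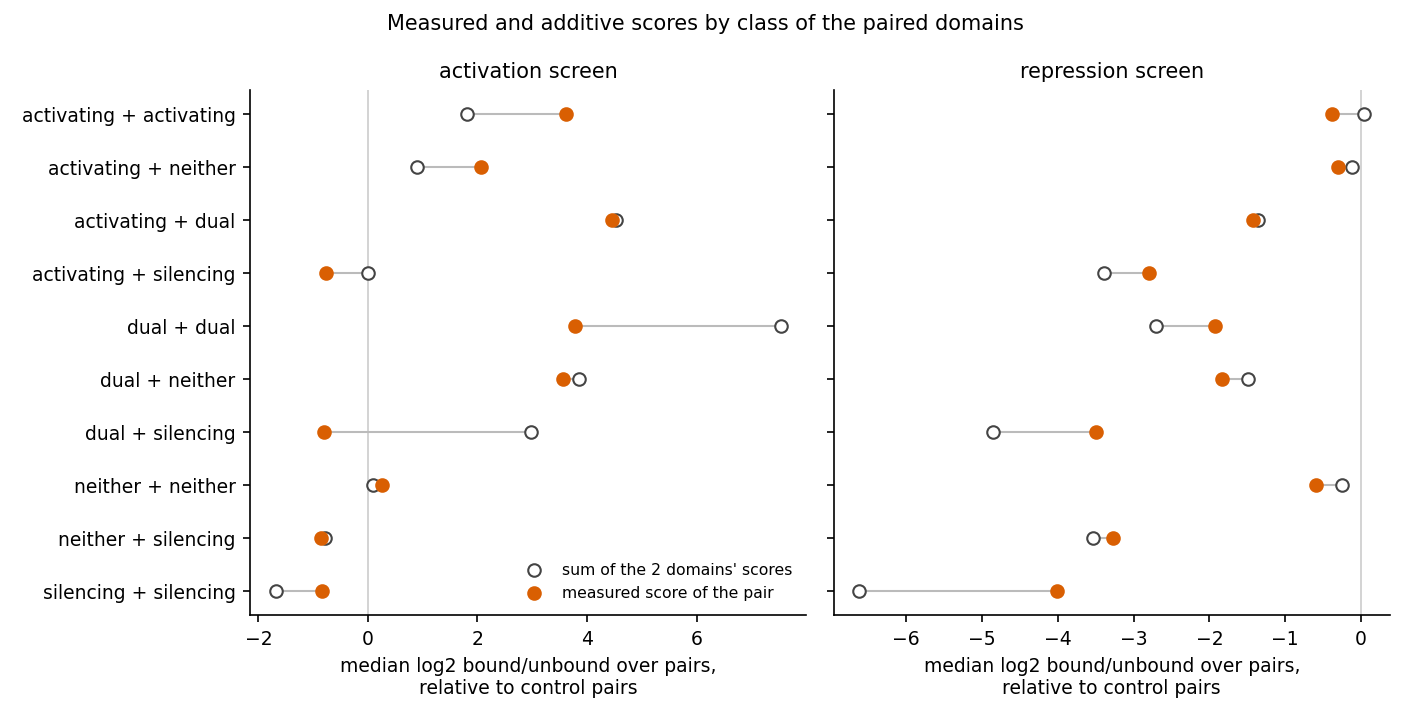
Median measured score (filled) and median sum of the single-domain scores (open) in log2 bound over unbound relative to control pairs (x axis), by class of both domains (y axis) in the activation and the repression screen. Pairs of activating domains exceed the sum (3.61 against 1.81), while pairs of dual domains in the activation screen (3.78 against 7.54, where the highest mean score of any pair was 6.32) and pairs of silencing domains in the repression screen (-4.00 against -6.62) lie closer to 0 than the sum.

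Silencing partners removed the effect of most activating domains in the activation screen. The effect of CRTC2 went from 1.58 next to controls to -0.88 next to 35 silencing domains (change -2.45, SE 0.32), and that of ANM2 from 1.33 to -0.80 (-2.14, SE 0.23). APC16, a subunit of the anaphase-promoting complex, changed by -1.75 (SE 0.19), ZN597 from 1.79 to 0.05 (-1.74, SE 0.16) and BTK by -1.12 (SE 0.16). For KIBRA the change of -2.47 (SE 0.58) did not pass the test (adjusted p = 0.146). The median change of the 6 activating domains was -1.94. The silencing partners' own effects, with a median of -0.59 beside controls in this screen, are not subtracted from it. Counted in the same way after the classes had been seen, 11 of the 12 activating and dual domains were lowered, MYBA from 4.36 to 0.10 (-4.25), NCOA2 from 3.93 to 1.23, FOXO3 from 3.76 to 0.57 and ZN473 from 3.33 to -0.31. In the other direction, the 6 activating partners had a median effect of 1.45 beside controls, which is not subtracted either. A rise beside them therefore does not show a change in the silencing domain. Beside these partners 5 of 35 silencing domains were higher than beside controls. These were the DNA-binding domains of ATF1 (1.5, SE 0.47), CREM (1.43, SE 0.25) and TERF1, a telomere protein (1.41, SE 0.19), the CXXC domain of KMT2B, a histone H3 methyltransferase (0.75, SE 0.14), and ID2 (0.41, SE 0.15). With the fixed lists CREM was -0.44 and KMT2B lost its call. The same partners lowered YAF2 (-0.73, SE 0.28) and a silencer tile (-0.40, SE 0.16; 0.13 without replicate 1). With the mean of scores in place of summed counts, 3 changes in place of 12 were called in the activation screen, and the calls of APC16, BTK, ZN597, ATF1, CREM and KMT2B were among those lost.

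In the repression screen, ANM2 (-2.72, SE 0.30), APC16 (-2.76, SE 0.34), CRTC2 (-2.83, SE 0.24) and KIBRA (-2.43, SE 0.42) were lower beside silencing than beside control partners. The partners' own effects are not subtracted. These partners were chosen for low effects in this same screen, with a median of -2.83 beside controls. Such a drop therefore does not show a change in the activating domain. Changes of BTK (-0.92, SE 0.46, adjusted p = 0.162) and ZN597 (-1.0, SE 0.45, adjusted p = 0.121) were not called, and the median change was -2.58. Activating partners raised TOX (1.71, SE 0.40), KMT2B (1.30, SE 0.42) and a pair of silencer tiles (0.66 and 0.66) among 35 silencing domains, and the median change of 0.21 became -0.08 with dual domains counted as activating. With the fixed lists KMT2B was -0.57 and TOX lost its call, and both lost it with dual domains counted. The 8 calls became 27 with the fixed lists and 26 with the mean of scores.

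**Figure D4:**
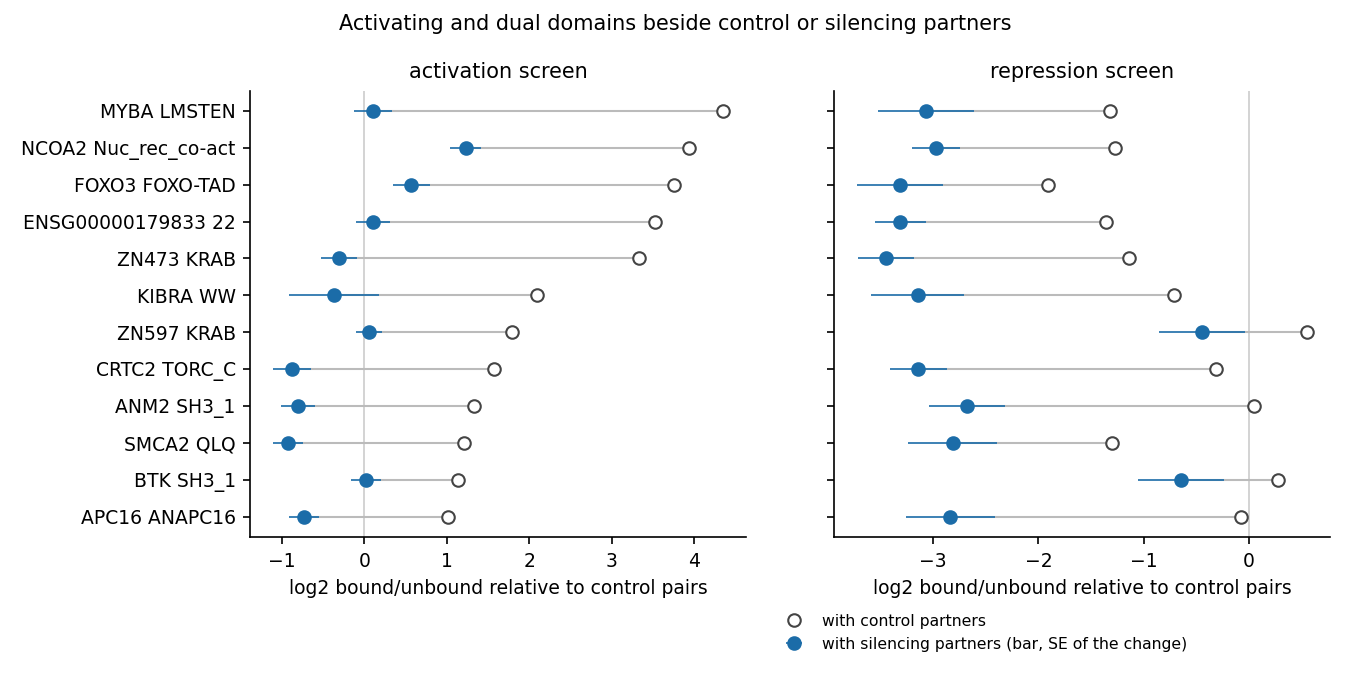
Log2 bound over unbound relative to control pairs (x axis) of the 12 activating and dual domains (y axis) with control partners (open) and with 35 silencing partners (filled; bars, SE of the change) in the activation and the repression screen. In the activation screen MYBA moves from 4.36 to 0.10 and CRTC2 from 1.58 to -0.88.

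On mean scores, limma called a difference between the positions of the fusion for 9 of 79 domains in the activation screen. Over the control domains the same difference had an SD of 0.41, above every SE printed here. The first position was higher for GSX1 (1.38, SE 0.23), CREM (1.04, SE 0.23), SMCA2 (0.90, SE 0.22), HXA13 (0.84, SE 0.22) and KMT2B (0.80, SE 0.23), and the second for KIBRA (-1.41, SE 0.23), STAT2 (-0.84, SE 0.22), JDP2 (-0.78, SE 0.22) and ANM2 (-0.66, SE 0.23). Control-partnered scores in both positions correlated with r = 0.924 across the 79 domains in the activation screen and 0.937 in the repression screen, where domains are not independent replicates. In the repression screen limma called 0 domains (14 at an unadjusted p of 0.05) and edgeR 0 (13 unadjusted). The 9 calls of the activation screen (20 unadjusted) rested on the mean over partners and the floor: medians gave 0 (12 unadjusted), a floor of 1 read gave 0 (12 unadjusted) and edgeR gave 1 (10 unadjusted).

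In the memory screen, 5 days after doxycycline was removed, the KRAB variants still had the lowest bound shares. Variant P21506 stood at -2.15 (SE 0.19; score -2.20 ± 0.51, SD, n = 2), 45.7% of its repression effect on the log2 scale, and the other KRAB variants at -1.82 (38.7%) and -1.65 (37.4%). Tile 18 of ENSG00000100307 stood at -1.24 (SE 0.14; 32.6%), CBX1 at -1.13 (SE 0.17; score -1.11 ± 0.78; 30.4%), a silencer tile at -1.06 (SE 0.15), MPP8 at -1.02 (SE 0.22) and HXA13, a homeobox protein, at -1.0 (SE 0.34). The call of HXA13 was lost without either replicate and under TMM over all members, which called 0 of 2 homeodomains. That of MPP8 was lost without replicate 1 (-0.53). The dual domains MYBA (-0.06, SE 0.13) and NCOA2 (-0.02, SE 0.14) were near 0, as was WWP2 of neither class (-0.03, SE 0.16). Each had a higher bound share than in the repression screen, by 1.26, 1.25 and 0.61. Under total counts these differences were -0.07, -0.09 and -0.72, where the control domains had a median of 0.45 in memory and 1.85 in repression. KIBRA stood at 0.64 (SE 0.17), with -0.21 in the first position alone and no call without replicate 1. IKKA, a kinase of the NF-kappa-B pathway, stood at 0.02, where its difference of 0.33 from the repression screen was not called (adjusted p = 0.128).

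By family, 4 of 4 domains in the KRAB repressor list were lower in memory (3 under total counts, with ZN777 DUF3669 above 0), as were 3 of 4 HP1 and chromodomain proteins (2 lower and 1 higher under total counts). Of 3 Polycomb and SAM/MBT domains 2 were lower, against 1 lower and 2 above 0 under total counts. Both SUMO and E3 domains and both homeodomains were lower (1 of each under total counts). DESeq2 called 1 of the 2 SUMO and E3 domains, and SUMO3 lost its call without replicate 1 (-0.63) and in the second position alone. TOX (-0.50) was lower as 1 of 2 in the corepressor and HDAC list, against 1 higher and 0 lower under total counts. The TOX call was lost without either replicate, with limma, with DMD partners, in each position alone and under both other scalings. Of 11 coactivator and Mediator domains 2 were lower (0 called by limma, 2 by DESeq2), against 9 higher under total counts, and of 5 WW domains 1 was higher. Among 5 domains each in the transcription factor and variant KRAB lists edgeR called 0 (0 at an unadjusted p of 0.05, 0 by limma and 0 by DESeq2), against 3 and 5 higher under total counts. Of 36 other domains 14 were lower and of 23 silencer tiles 13, where total counts left 3 of the 36 lower and 13 higher. The counts adjusted over the list alone were the same except for 3 Polycomb and SAM/MBT domains in place of 2 and 1 coactivator and Mediator domain in place of 2. Over all domains edgeR called 30 of 79 lower and 1 higher (KIBRA), against 10 calls without replicate 1 and 21 without replicate 2.

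Of the 57 domains lower in the repression screen, 28 were lower in memory, 1 was higher and 28 were not called, with a median of -0.38 in memory against -2.03 in repression. The difference between both screens was called for 48 of 79 domains, 47 with a higher bound share in memory and 1, DPF1, with a lower one (-1.06, SE 0.24). Total-count scaling moved the median of all members in memory by 0.50 and TMM over all members by 0.56, and the 48 calls became 23 higher and 38 lower under total counts.

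**Figure D5:**
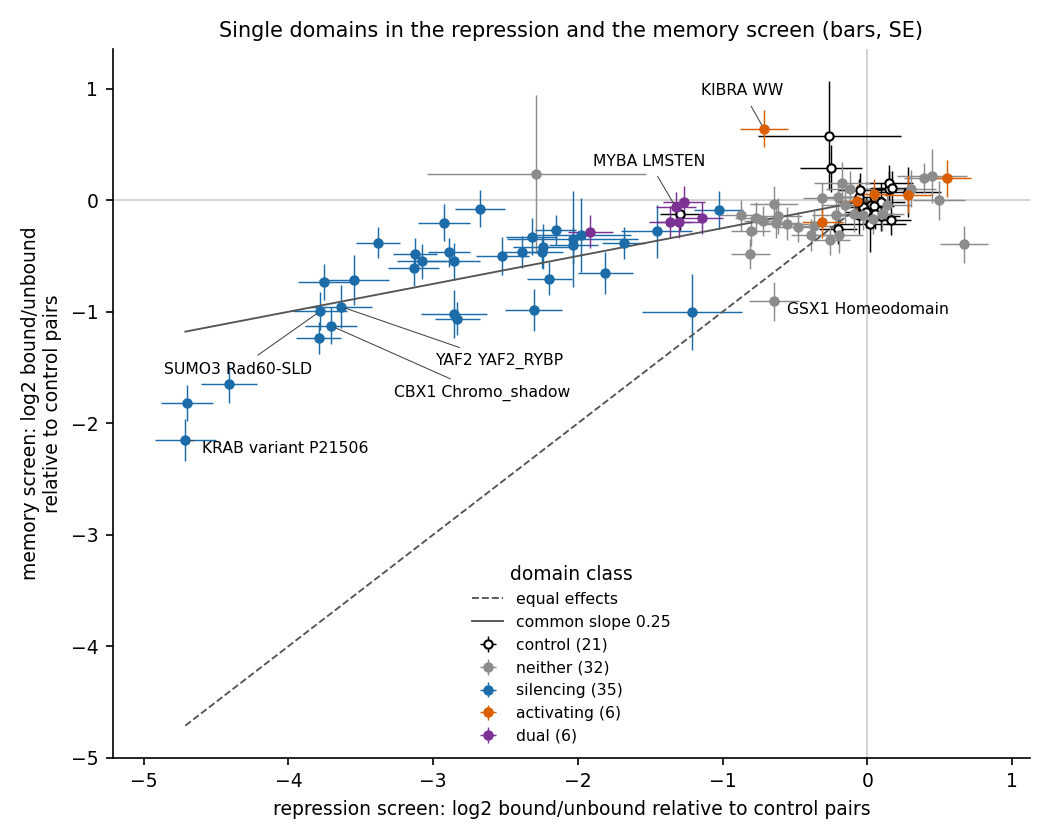
Log2 bound over unbound relative to control pairs of the 100 domains next to control partners in the repression screen (x axis) and the memory screen (y axis), with SE as bars, a dashed line of equal effects and a solid line with the common slope of 0.250. KRAB variant P21506 lies at -4.71 and -2.15, and MYBA at -1.32 and -0.06.

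Among pairs in the memory screen, the lowest held DMD tile 182 in the first position, with PCGF2 (-7.78, SE 2.09), with silencer tiles (-6.83, SE 1.13, and -6.0, SE 1.53) and with random control 205 (-4.99, SE 1.27). Next was DPF1 + KRAB variant P21506 (-4.75, SE 0.81). In the bound libraries of replicates 1 and 2, DMD tile 182 + PCGF2 had 0 and 2 reads. Its pairs with silencer tiles had 9 and 2, and 1 and 14 reads there, and that with random control 205 had 20 and 23. High pairs were WBP4 + SSX2 (4.59, SE 1.00), CREM + KIBRA (4.32, SE 1.03), WWP2 + KIBRA (3.55, SE 0.60) and WBP4 + DMD tile 255 (2.86, SE 0.78). Members with a KRAB variant made up 48.6% of the lower members: 322 of 573 tested with one were lower (56.2%), against 3.89% of the others. Of 9337 members edgeR called 663 lower and 24 higher, and 2 of 420 control pairs. The 687 calls became 1 without replicate 1 and 422 without replicate 2, and each of the pairs named here lost its call without replicate 1. Under both other scalings the pairs of DMD tile 182 kept a call with 1 silencer tile only, and the pairs PCGF2 with DMD tile 182, WWP2 + KIBRA and WBP4 + DMD tile 255 lost their calls without the block. Of the pairs named here only WWP2 + KIBRA and DPF1 + KRAB variant P21506 kept a call without replicate 2. The difference between memory and repression was called for 3677 members as higher and 54 as lower of 8935, against 1226 and 1113 under total counts and 1245 and 1311 under TMM over all members.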

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

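The tests on same-domain pairs, on the dual domains and on the common slope of the memory screen were all chosen after the results had been seen. Each difference below was flagged because the test of the difference between 2 screens passed an adjusted p of 0.05.

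The activation and repression effects of all 6 dual domains differed: MYBA by 5.68, FOXO3 by 5.67 and NCOA2 by 5.20. Tile 22 of ENSG00000179833 differed by 4.89, ZN473 by 4.48 and SMCA2 by 2.51. The class was defined by at least 1 in activation and at most -1 in repression, so its definition fixed such differences. They are no further support for the pattern, and the screens differed in reporter line and days of doxycycline. Under total-count scaling ZN473 stood at 0.69 in the repression screen, where the control domains had a median of 1.85. The memory effects of the dual domains were not called. DMD tile 31, a control by name, showed the same pattern (2.09 in activation, -1.29 in repression). The highest of the dual domains' median member scores in the repression screen was -0.99, which argues against a few members with most of the reads. Exchanged fraction labels in this screen would have raised silencing domains, but the median repression effect of the KRAB variants was -4.70. This argues against an exchange only if bound is the ON fraction, which the labels do not state. The effects of the KRAB variants were also known when this test was written. An effect of strong activation on the reporter or the cells stays open, since across the 6 activating domains outside the dual class, too few to decide, Spearman rho between both effects was -0.257 (exact permutation p = 0.658).

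The memory and repression effects differed for 3731 members and 48 domains, among them the KRAB variants (2.88, 2.76 and, for P21506, 2.56), CBX1 (2.58), tile 18 of ENSG00000100307 (2.55), KIBRA (1.36), MYBA (1.26), NCOA2 (1.25) and WWP2 (0.61). Under TMM over all members the last 4 were -0.0490, -0.15, -0.16 and -0.79, where the control domains had a median of 0.52 in memory and 1.98 in repression. WWP2 also lost its call without replicate 1, without the block and in each position alone. A common linear compression of the memory screen, as from poorer separation, would leave every domain on a single slope apart from noise. With edgeR, 9 domains departed from the common slope of 0.250 at an adjusted p of 0.05 (against a limit of 5, itself written after the effects had been seen). The 3 KRAB variants, GSX1 and DPF1 were lower and KIBRA and 3 silencer tiles higher. The slope was fitted on the same 79 effects and taken as known. More noise, or a compression that is not linear, would also move domains off it, so the test cannot decide against these. The departures correlated between the replicates across the 79 domains (Spearman rho = 0.389), which is consistent with a return of the reporter to the ON state that differs between domains, as a hypothesis. The lower agreement of the memory replicates limits this reading, since 10 domains in place of 31 were called in memory without replicate 1.

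Pairs of the same domain held 11.02% of the reads in 1.00% of the members, and this pattern was weighed because it touches every library. Unequal cloning alone would move bound and unbound fractions alike, but same-domain control pairs had a median score of 3.33 in memory replicate 1 (3.00 SD of the other control pairs) and -0.02 in replicate 2. An effect of 2 copies of an active domain is not the sole source, since control domains held the excess as well. The median share of a domain's reads in its own pair was 0.770 times as large for other domains (3.00%) as for controls (3.89%). The other domains include 32 of neither class and the reads come from all libraries, so a smaller contribution of activity cannot be excluded. What stays open is that pairs formed during amplification or sequencing may add to these members, because their share of the control-pair reads ranged 8.99-fold between libraries, from 7.60% (95% Wilson interval 7.56 to 7.64%) in the memory unbound library of replicate 1, where the next lowest was 22.1% in another library, to 68.3% (68.1 to 68.4%) in the repression unbound library of replicate 1. No biological explanation beyond that of 2 copies was tested.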

How the results depend on the processing

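The alternatives without DMD tile 31, without same-domain pairs and with dual domains counted as activating were chosen after the data had been seen. Of the summary counts and correlations, 105 stayed within 1.5 times or within their spread and 34 moved. Of the values for named items and medians 1491 kept direction and call or changed sign without a call in either fit, 167 kept the direction but lost the call, 12 gained a call, 59 moved and 35 reversed. The activation effects of MYBA, NCOA2 and FOXO3 and the memory effect of CBX1 kept their calls under every alternative run. The cause was not tested except where the construction shows it (fewer reads, partners or replicates).

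Scaling changed counts and directions, because it moved the 0 of each screen. The control domains had medians of -0.91, 1.85 and 0.45 in activation, repression and memory under total counts. Under TMM over all members these were 0.24, 1.98 and 0.52. A sign that reversed below is therefore not a reversal relative to the controls. Under total counts, activation members gave 5592 calls (1020 higher, 4572 lower, against 1344 and 860), memory members 310 (63 and 247, against 24 and 663), memory versus repression 2339 (1226 and 1113, against 3677 and 54) and memory domains 47 (36 and 11, against 1 and 30). TMM over all members gave 358 memory members (105 and 253). Counts that stayed within 1.5 times still split differently: repression members 2593 higher and 2811 lower under total counts and 2846 and 2688 under TMM over all members (47 and 5124 otherwise), repression domains 43 and 27, and 45 and 22 (4 and 57 otherwise), activation domains 9 and 64 under total counts (25 and 28 otherwise), memory domains 30 and 8 under TMM over all members, memory versus repression 1245 and 1311 under it, and its domains 23 and 38, and 21 and 37 (47 and 1 otherwise). Reversed under total counts were, in repression, HXA13 (0.62), KIBRA (1.12), KMT2B (0.0212) and ZN473 (0.69), in memory ZFP28 (0.25), and in memory minus repression IKKA (-1.01), MYBA (-0.0744), NCOA2 (-0.0850) and WWP2 (-0.72). Reversed under TMM over all members were, in repression, FOXO3 (0.0527), HXA13 (0.75), KIBRA (1.25), KMT2B (0.16) and ZN473 (0.82), in memory TOX (0.0603), and in memory minus repression IKKA (-1.08), KIBRA (-0.0490), MYBA (-0.15), NCOA2 (-0.16) and WWP2 (-0.79).

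Other settings also moved results. Memory members numbered 687, but 1497 with DESeq2, 1043 with the 4 libraries of the screen alone and 255 beyond 2 SD of the control pairs, a limit that gave 955 activation members (2204 otherwise). Memory domains numbered 31, but 19 with limma, 14 with DMD partners and 15 in position 2, where activation domains numbered 34 (53 otherwise), and KIBRA in memory was -0.21 in position 1. Memory versus repression counted over the 79 control-partnered domains gave 48. Against the stronger effect, repression deviations numbered 1021 (478 above, 543 below; 2089 otherwise), and medians reversed for activating with dual domains in activation (0.77) and for dual (-0.26), dual with silencing (-0.0444) and silencing pairs (-0.0225) in repression; activating with dual pairs in repression were 0.0448 with the mean over partners. Mixed pairs in activation (12 calls) gave 26 with the fixed lists, 3 with the mean of scores and 24 with dual domains counted as activating, and in repression (8 calls) 27 with the fixed lists, 26 with the mean of scores and 21 with the mean of scores at a floor of 1 read. With the fixed lists CREM in activation was -0.44 and KMT2B in repression -0.57. The median change of silencing domains reversed in activation with the mean of scores (0.0744), the same at a floor of 1 read (0.10) and without replicate 1 (0.10) or 2 (0.00848), and in repression with the fixed lists (-0.13) and dual domains counted (-0.0773); a silencer tile in activation was 0.13 without replicate 1 and -0.53 without replicate 2. Position calls in activation (9, of 20 unadjusted) were 0 with medians (limma, 12 unadjusted), 0 with a floor of 1 read (limma, 12 unadjusted) and 1 with edgeR. Replicate correlations of 0.798, 0.802 and 0.318 were 0.845, 0.852 and 0.391 with 200 reads, and the first and second 0.751 and 0.786 with a floor of 1 read.

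Leaving out a replicate, with the lone replicate assumed to vary like the other screens, gave 936 to 1081 activation members (fewer without replicate 1), 1 (without replicate 1) to 422 (without replicate 2) memory members, and 10 (without replicate 1) to 21 memory domains. The other ranges were 4118 to 5134 repression members, 2796 to 4320 for memory versus repression, 38 to 46 activation domains, 55 to 56 repression domains and 41 to 42 domains for memory versus repression. Deviations, mixed pairs and position had no test with a replicate left out. Without the replicate block, which pairs the fractions of an infection, members numbered 2276, 5212 and 706 and memory versus repression 3662, and domains 53, 61, 28 and 47. The block added the calls of 7 of the pairs followed here and of WWP2 in memory versus repression and changed no other call among the items followed. The activation unbound library of replicate 2 was the shallowest, with a median of 28 reads per member.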

Other observations

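The order test was planned before the result was seen. The tests on the overlap of lower domains, on pairs by domain and on DMD tiles were chosen after the results had been seen.

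Several domains outside the activating class, paired with partners of neither class, exceeded the sum of both median control-partnered scores in the activation screen. SMRC2, a SWI/SNF subunit, was above the sum in 35 of 62 such pairs (median deviation 1.60) with a single effect of 0.61, IKKA in 31 of 61 (0.98), STAT2, an interferon-responsive transcription factor, in 31 of 61 (0.99) and WBP4, a WW-domain protein, in 29 of 61 (1.22). Of the activating class, APC16 and BTK were above it in 35 of 63 pairs each (1.75 and 1.58), ANM2 in 32 of 64 and CRTC2 in 32 of 63. KIBRA, a WW-domain protein as WBP4 and WWP2 are, had the highest single effect in memory and stood in 2 of the 5 highest memory pairs.

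With control-pair scaling, all domains lower in the activation screen were also lower in the repression screen (28 of 28, or 100%, where independent lists of 28 and 57 among 79 domains would share 20.2; Fisher's exact p = 1.07e-05). Under total counts this cannot hold, as 64 domains were lower in activation and 27 in repression. The screens share the control domains but no libraries. The overlap is consistent with the hypothesis that domains lower in the activation screen are silencing domains, under control-pair scaling.

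The scores of a pair and of the same pair in the other order, each taken from the other replicate, correlated across pairs with r = 0.798 in activation and 0.738 in repression, against 0.840 and 0.790 between replicates of the same order. The lower ratio of both screens was 0.934, above the 0.9 set beforehand for the hypothesis that order matters little. In memory the ratio was 0.648 (0.229 against 0.354), below that limit, so that hypothesis is not borne out there.

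DMD tile 31 was higher in 23 of 41 of its control pairs in activation, lower in 24 of 40 in repression and called in 0 of 39 in memory. DMD tile 182 in the first position was lower in 6 of 62 memory pairs. The share of its repression effect left in memory was 82.4% for HXA13 and 141% for GSX1, both homeodomains, and their differences between the screens were not called by edgeR (adjusted p = 0.701 and 0.362). Under total counts HXA13 stood at 0.62 in repression, against a median of 1.85 for the control domains.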
